A study of Homo sapiens with 9 samples.

How the data were processed

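HEK293T cells are a human embryonic kidney line. RNA immunoprecipitation sequencing (RIP-seq) was applied to recover RNA bound to CCR4-NOT, the main cytoplasmic deadenylase complex, through V5-tagged CNOT7, a nuclease subunit carrying a substitution that impairs catalysis. Per the labels, the series held 3 RIP libraries, 3 input libraries from cells given doxycycline at 3 µg/mL for 24 h, and 3 input libraries from cells without it. RNA labelled as cytoplasmic was extracted with Trizol, depleted of ribosomal RNA and read as single ends of 75 bp on an Illumina NextSeq instrument. The submitters' processing notes name STAR, featureCounts and DESeq2, without versions, and the build GRCh38. The annotation release, the strand setting and the low-count filter are not given in the sources used here.

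The deposited table held 30956 genes. The values of the 3 RIP libraries are a signal, gene counts that the authors had divided by 1 size factor per library. Each value was a whole multiple of the smallest value in its column within 0.01 of a read (100% of values), so whole reads were recovered. The log2 fold change of RIP over input, its standard error (SE), the Wald statistic (a score equal to the fold divided by its SE), the p-value and the Benjamini-Hochberg adjusted p-value were computed by the authors with DESeq2, per the file headers. A shrunken log2 fold change was deposited too, by a method not given in the sources used here. The deposited mean normalized count was an average over 9 libraries: 9 times this mean was below the sum of the RIP values for 0 genes and equal to it, within a relative 1e-09, for 3245.

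The names of 3 input columns matched both kinds of input library, with and without doxycycline, so these columns were not used here. The planned quasi-likelihood tests on counts could not be run without them. The comparison of RIP with input therefore rests on the authors' deposited table, and the comparison of inputs with and without doxycycline was not analysed here. Which cells the RIP libraries came from, and which input libraries the authors compared them with, is not given in the sources used here. No immunoprecipitate from cells without the tag was analysed here, so nonspecific recovery was not subtracted.

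The mean of the compared inputs was derived as the RIP mean divided by the fold in the authors' deposited table, which takes that fold as a ratio of group means. The mean of all 6 inputs was derived from the mean over 9 libraries and the RIP values. Neither has an SD. For genes without input reads the derived mean follows from the fitted fold and is no measurement. Genes with an adjusted p in the authors' deposited table (20649) were taken as tested, with a threshold of 0.05, and a second count required at least a 2-fold change. The remaining 10307 genes had no adjusted p and stayed out of the main counts of enriched and depleted genes.

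A total of 31 gene lists, fixed before the data were examined, were tested with limma's camera test on the authors' Wald statistic, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists with at least 5 tested members. The test was repeated with a correlation estimated from the 3 RIP libraries, on log2 values with a pseudocount of 1. It was also run on simulated lists, with the SEs of the 20649 genes and drawn folds. It recovered 77% of 200 lists shifted by 1 on the log2 scale, 9% shifted by 0.5 and 1% shifted by 0.25. Of 400 unshifted lists it called 0.75%, 0.5% and 0%. Simulated genes were drawn independently, so these shares do not cover lists whose members vary together.

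Genes were named by a rule fixed in advance: the subunits of CCR4-NOT, the 10 largest folds in each direction among called genes with a mean of at least 5 CPM, and the 3 members of each list with the smallest p. The rule also required every library of a group to lie above every library of the other. Without input libraries this became every RIP library on the same side of the derived input mean. Symbols of unnamed transcripts, small RNAs and pseudogenes were left out of the largest folds. Other members named in the text were chosen after their values were seen. A few genes that the rule names are not reported here.

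Locations were matched by symbol to a RefSeq gene table of GRCh38.p14, which gave a position for 84.02% of tested genes. No genome sequence was used here. The 3 RIP libraries held 37140622, 40764899 and 38229122 reads in genes, so that 3 reads, the floor for a gene at 0, stood for 0.0736 to 0.0808 CPM, for counting error only. Reads without molecular identifiers are not independent molecules. Chi-square per degree of freedom between pairs of RIP libraries was 52.5 to 61.0, so no pair differed by sampling noise alone. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries.

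Alternatives covered total-count scaling, removal of small and mitochondrial RNA genes, low-count filters, all 6 inputs as 1 group, omission of each RIP library and the list correlation. Where these changed the folds, the authors' SE was kept. Calls with all 6 inputs therefore hold no spread among those inputs. They also pool inputs with and without doxycycline, so a change there can come from another reference and not from processing. Shrunken folds, an adjusted p under 0.01, a mean normalized count of at least 1000, protein-coding genes alone, ranks and shrunken folds in the list test were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.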

Results

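RNA that co-purified with V5-tagged, catalytically impaired CNOT7 was compared with input RNA from HEK293T cells. CNOT7 is 1 of the nuclease subunits of CCR4-NOT, the complex that shortens poly(A) tails and so starts the decay of most mRNAs. The data comprised 3 RIP libraries and, through the authors' deposited table, the folds of RIP over 3 of the 6 input libraries. The RIP libraries held 37140622, 40764899 and 38229122 reads in genes. Spearman correlations between RIP libraries were 0.97 to 0.98 across 12402 tested genes, which are not independent replicates. These genes had a mean normalized count of at least 100. Pearson correlations of their log2 values were 0.91 and 0.92 for replicate 2 with replicates 1 and 3, and 0.98 between replicates 1 and 3. RIP replicate 2 differed from the others at low counts: 14786 genes had no read in it, against 6720 in replicate 1 and 6398 in replicate 3. Among genes with 30 to 100 reads on average in replicates 1 and 3, 38.6% had no read in replicate 2, and among genes with 300 to 1000 reads 0.0998% had none.

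Which RNAs associate with the complex was the question of the comparison of RIP with input. AU-rich and immediate-early, zinc finger and HOX mRNAs were recovered above input. Ribosomal protein, histone, respiratory chain and mitochondrially encoded RNAs were recovered below it. Of 20649 tested genes in the authors' deposited table, 4254 were enriched and 4108 depleted at an adjusted p (DESeq2) under 0.05, and 2123 and 1989 of them changed at least 2-fold. All 3 RIP libraries lay on the called side of the derived input mean for 4199 of the enriched and 4088 of the depleted genes in the authors' deposited table. The RIP mean lies on that side by construction, so this describes only the spread between RIP libraries, not between inputs. The median fold of all tested genes in the authors' deposited table was -0.079 on the log2 scale, so directions are relative to a typical gene. Scaling by total counts raised every fold by 0.50 on the log2 scale, and mitochondrially encoded RNA made up 22.8% of the derived input and 1.03% of RIP. Under that scaling the authors' deposited table gave 6994 enriched and 2055 depleted genes, 77.3% enriched against 50.9% with the authors' scaling. Removal of small and mitochondrial RNA genes raised the folds by 0.13 and gave 4908 and 3404 genes from the authors' deposited table.

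**Figure D1:**
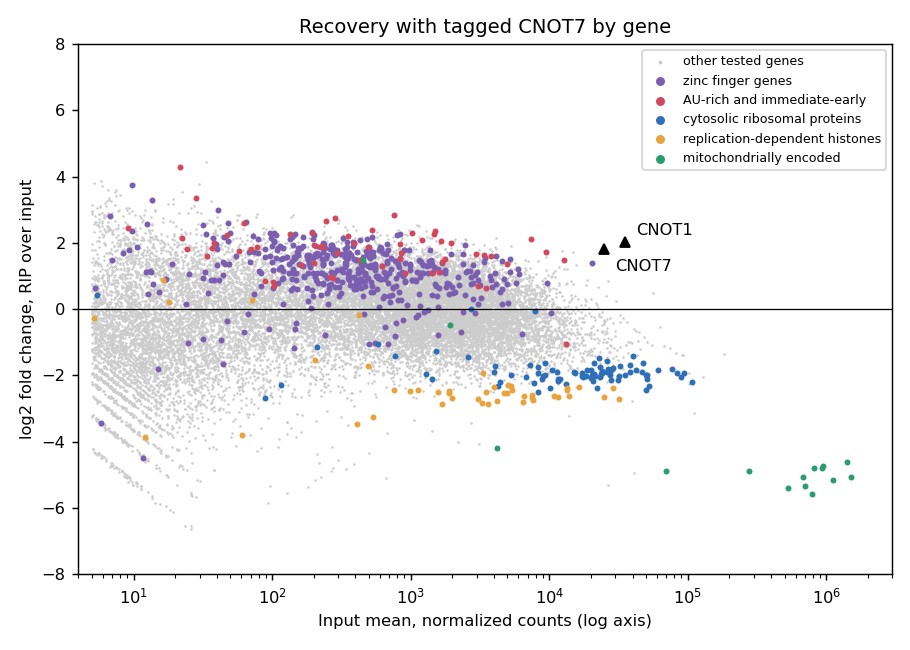
Each point is a tested gene with a derived input mean of at least 5 normalized counts, set by that mean (x, log axis) and its log2 fold of RIP over input in the authors' deposited table (y), with 5 gene lists in colour and CNOT1 and CNOT7 as triangles. AU-rich and immediate-early and zinc finger genes lie mostly above 0, and ribosomal protein, histone and mitochondrially encoded genes mostly below it, with list medians of 1.85, 1.17, -1.94, -2.51 and -4.89.

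CNOT1, the scaffold of the complex, gave the most abundant RNA in each RIP library, and the bait's own mRNA came next in the RIP mean. CNOT1 (ENSG00000125107, chromosome 16, 58519951 to 58629826, GRCh38.p14) had 144350 ± 1397 normalized counts in RIP (SD, n = 3) against a derived input mean of 35315. Its log2 fold in the authors' deposited table was 2.03 (SE 0.10). CNOT7 (ENSG00000198791, chromosome 8, 17224966 to 17246857) had 86982 ± 11495 (SD, n = 3) against 24800, a log2 fold of 1.81 (SE 0.11) in the authors' deposited table. Gene counts do not separate endogenous CNOT7 from tagged CNOT7. Of the 11 subunit genes tested, 6 rose and 2 fell in the authors' deposited table, with the same counts adjusted over the list alone. The list lay above other genes (limma camera, adjusted p = 0.00029). It holds the bait and CNOT1, and the test was not run without them. That call therefore does not speak for the other subunits as a set. The ubiquitin ligase CNOT4, the nuclease CNOT8 and CNOT2 rose with log2 folds of 0.95, 0.78 and 0.74 in the authors' deposited table. CNOT10 and CNOT11, which form a module together, fell with log2 folds of -0.40 and -0.36 in the authors' deposited table, and turned to 0.092 and 0.13 under total-count scaling. CNOT11 was also not called without RIP replicate 1 (-0.27) or without small and mitochondrial RNA genes (-0.23). With all 6 inputs as 1 group CNOT7 had 2.58, as the remaining inputs held less of it (4240 normalized counts). The nucleases CNOT6 and CNOT6L (0.26 and 0.27) and CNOT3 (-0.029) did not pass the test in the authors' deposited table. CNOT6 and CNOT6L passed under total-count scaling (0.76 and 0.77), without small and mitochondrial RNA genes (0.39 and 0.40), with all 6 inputs (0.40 and 0.47) and without RIP replicate 3 (0.35 each). CNOT9, at 0.30 in the authors' deposited table, no longer passed with all 6 inputs (0.20), without RIP replicate 2 or 3 (0.25 each) or at an adjusted p under 0.01.

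The mRNAs of proteins that bring CCR4-NOT to its targets rose as a list. Of 34 adaptor and recruiter genes, 27 rose and 2 fell in the authors' deposited table (the same counts adjusted over the list alone, median log2 fold 1.10, limma camera adjusted p = 2.7e-17). An estimated correlation gave an adjusted p (limma camera) of 0.00021. In the authors' deposited table, the antiproliferative factors BTG2 and BTG3 had log2 folds of 2.06 (SE 0.13) and 1.71 (SE 0.11), and the AU-rich element binding proteins ZFP36L2 and ZFP36 had 1.98 and 2.66. TOB1 and PUM2 stood at 1.80 and 1.24 in the authors' deposited table. AGO1 and SAMD4B were the members that fell in the authors' deposited table, to -0.27 and -0.24, and lie above 0 under total-count scaling, which adds 0.50.

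Immediate-early and AU-rich mRNAs formed the list with the highest median. Of 63 members 56 rose and 1 fell in the authors' deposited table (57 and 1 adjusted over the list alone), with a median log2 fold of 1.85 (limma camera, adjusted p = 1.4e-34). NFKBIA, the inhibitor of NF-kappaB (chromosome 14, 35401513 to 35404749), had 5354 ± 809 normalized counts in RIP (SD, n = 3) against a derived input of 755. Its log2 fold in the authors' deposited table was 2.83 (SE 0.14). The transcription factor KLF6 and the kinase PIM1, also among the 3 members with the smallest p, had 2.35 (SE 0.11) and 2.29 (SE 0.12) in the authors' deposited table. Several of the largest folds belonged to mRNAs scarce in input. In the authors' deposited table, the cytokine signalling inhibitor SOCS3 had a log2 fold of 4.30 (SE 0.44), from a derived input of 21.6 to 425 ± 33 normalized counts in RIP (SD, n = 3). The Notch target HES5 (chromosome 1, 2528745 to 2530263) rose by 4.45 (SE 1.09) in the authors' deposited table, from 33.4 to 729 ± 222 (SD, n = 3), with a shrunken fold of 2.63. FOS and the beta-1 adrenergic receptor ADRB1 rose by 3.36 (SE 0.47) and 3.28 (SE 0.54) in the authors' deposited table, and by 2.96 and 3.03 without RIP replicate 2. The remaining genes among the 10 largest enrichments in the authors' deposited table were CBR3-AS1 (3.78), an antisense RNA, ZNF443 (2.98), IL12A (2.86), SEMA7A (2.84) and PGBD2 (2.84). The shrunken fold of CBR3-AS1 was 2.96, and PGBD2 had 1.66 with all 6 inputs as 1 group. With the strand setting unknown, reads of CBR3-AS1 cannot be told from those of overlapping genes.

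Targets of PUMILIO proteins and microRNAs also rose as lists. Of 44 PUMILIO-regulated mRNAs, 26 rose and 5 fell in the authors' deposited table (27 and 5 adjusted over the list alone), with a median log2 fold of 0.60 (limma camera, adjusted p = 5.2e-06). With an estimated correlation this list had an adjusted p (limma camera) of 0.029. Its leading members in the authors' deposited table were the cell cycle inhibitor CDKN1B at 2.36 (SE 0.15), E2F3 at 1.93 (SE 0.10) and DDIT4 at 1.91 (SE 0.12). Of 38 let-7 and miR-17 family targets, 22 rose and 5 fell in the authors' deposited table (25 and 8 adjusted over the list alone, median 0.50, limma camera adjusted p = 5.7e-05). Their adjusted p with an estimated correlation (limma camera) was 0.020. TXNIP (1.04 with all 6 inputs) and the apoptosis factor BCL2L11 rose by 2.01 and 1.98 in the authors' deposited table, while the chromatin protein HMGA1 had -1.62 and the RNA-binding proteins IGF2BP1, IGF2BP2 and IGF2BP3 had -0.65, -0.68 and -0.59. Of 25 p53 targets, 15 rose and 3 fell in the authors' deposited table (the same counts adjusted over the list alone, median 0.61, limma camera adjusted p = 0.0045). BTG2 and TNFRSF10B, a death receptor, rose by 2.06 and 1.18 and CCNG1 had -1.33 in the authors' deposited table. With all 6 inputs as 1 group the p53 list's median was -0.42 and its adjusted p (limma camera) 0.185, and TNFRSF10B, at 0.10, was no longer called.

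Transcription factor genes rose as families. Among 452 zinc finger genes with ZNF symbols, 339 rose and 8 fell in the authors' deposited table (352 and 9 adjusted over the list alone), with a median log2 fold of 1.17 (limma camera, adjusted p = 8.7e-25). ZNF764, ZNF275 and ZNF503 had log2 folds of 2.26, 1.59 and 1.52 in the authors' deposited table. Short reads shared between these paralogs can be split between them. Among 38 HOX genes, which encode developmental homeobox factors, 28 rose and 0 fell in the authors' deposited table (the same counts adjusted over the list alone, median 0.98, limma camera adjusted p = 3.7e-12). HOXB3, HOXA5 and HOXA9 rose by 1.82, 1.81 and 1.40 in the authors' deposited table, and the first 2 by 1.20 and 1.08 with all 6 inputs.

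**Figure D2:**
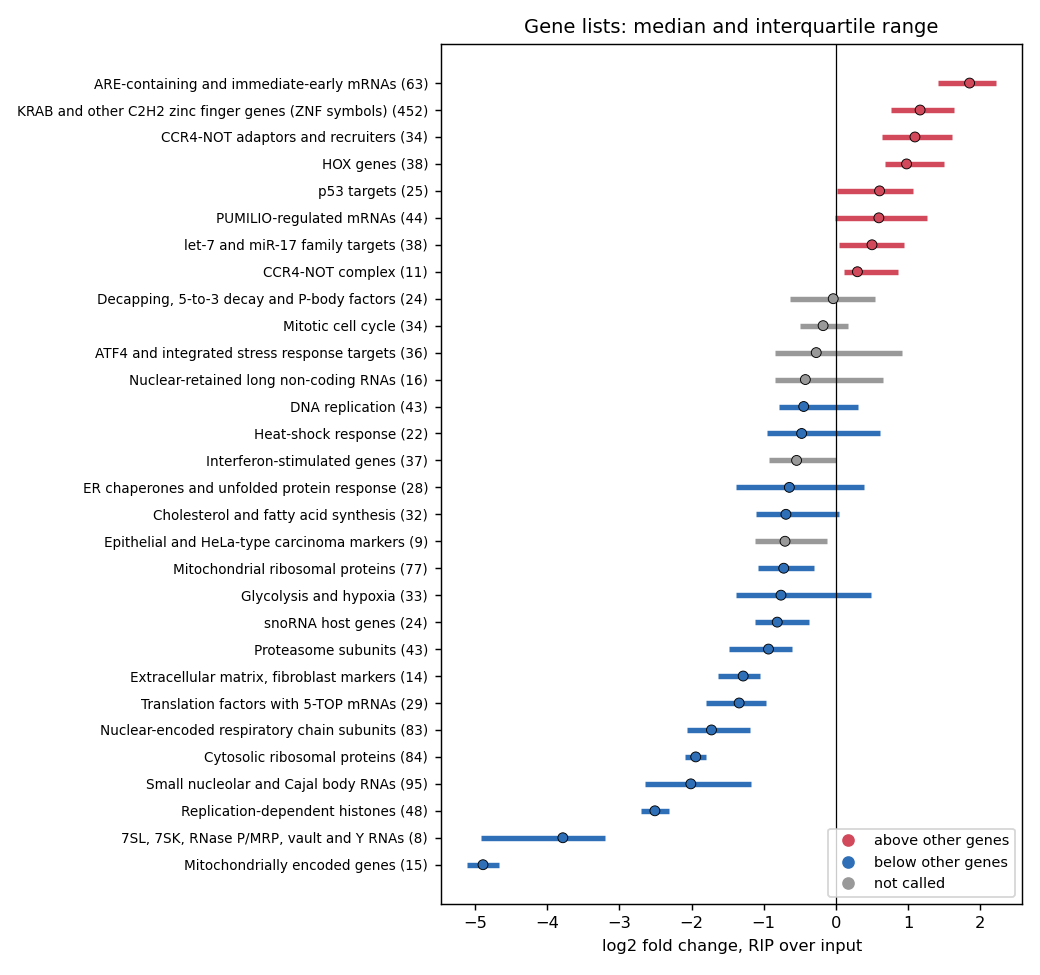
Median (point) and interquartile range (bar) of the log2 fold of RIP over input in the authors' deposited table for the 30 tested gene lists, with the number of tested members in parentheses and colour for the call of limma's camera test at a correlation of 0.01. Of these lists 8 lay above other genes, 16 below and 6 were not called, with medians from -4.89 for mitochondrially encoded genes to 1.85 for AU-rich and immediate-early mRNAs.

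RNAs of the mitochondrial genome had the lowest list median. Of 15 such genes 13 fell and 0 rose in the authors' deposited table (the same counts adjusted over the list alone), with a median log2 fold of -4.89 (limma camera, adjusted p = 1.1e-118). MT-CO1, a cytochrome oxidase subunit, had 57674 ± 1818 normalized counts in RIP (SD, n = 3) against a derived input of 1405555, a log2 fold of -4.61 (SE 0.14) in the authors' deposited table. MT-ND2 had -5.40 (SE 0.17) in the authors' deposited table, and the 10 largest depletions named by the rule were all mitochondrially encoded, from -5.40 to -4.61. Nuclear genes for the respiratory chain fell too, 73 of 83 with 0 rising in the authors' deposited table (74 adjusted over the list alone), with a median of -1.72 (limma camera, adjusted p = 3.8e-32). With an estimated correlation their adjusted p (limma camera) was 0.0044. COX8A, UQCR10 and UQCRH had log2 folds of -2.69, -2.13 and -2.10 in the authors' deposited table. Of 77 mitochondrial ribosomal protein genes, 47 fell and 3 rose in the authors' deposited table (the same counts adjusted over the list alone, median -0.72, limma camera adjusted p = 3.4e-06). That call did not hold with an estimated correlation (adjusted p = 0.289).

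The mRNAs of the translation machinery fell almost as a block. Of 84 cytosolic ribosomal protein genes 81 fell and 0 rose in the authors' deposited table (the same counts adjusted over the list alone), with a median log2 fold of -1.94 (limma camera, adjusted p = 9.5e-86). An estimated correlation (0.54) gave an adjusted p (limma camera) of 0.00024. RPL32 had -2.32 (SE 0.13) in the authors' deposited table. Reads of these genes can be shared with their many processed pseudogenes. Of 29 translation factors whose mRNAs carry a 5' terminal oligopyrimidine tract, 26 fell and 1 rose in the authors' deposited table (27 and 1 adjusted over the list alone, median -1.34, limma camera adjusted p = 5.7e-35). In the authors' deposited table the ribosomal scaffold RACK1 had -2.07, the elongation factor EEF1A1 -1.94 and BTF3 -1.80, while the helicase EIF4A2 had 0.90.

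Histone mRNAs and several classes of non-coding RNA fell as well. Of 48 replication-dependent histone genes, whose mRNAs typically end in a stem-loop, 39 fell and 0 rose in the authors' deposited table (40 adjusted over the list alone), with a median of -2.51 (limma camera, adjusted p = 1.9e-46). Whether the reads came from stem-loop or polyadenylated transcripts was not examined here. H2BC21, H2BC12 and H2BC5 had -2.66, -2.63 and -2.45 in the authors' deposited table, though near-identical histone copies can share reads. With all 6 inputs the list's median was -3.21 and H2BC12 had -3.29. All 8 tested 7SL, RNase MRP, vault and Y RNAs fell in the authors' deposited table (the same count adjusted over the list alone, median -3.79, limma camera adjusted p = 3.6e-16). RNY1, RN7SL3 and RMRP had -4.08, -3.22 and -2.76 in the authors' deposited table. Of 95 small nucleolar and Cajal body RNAs 20 fell and 0 rose in the authors' deposited table (14 adjusted over the list alone, median -2.01, limma camera adjusted p = 0.032). SNORD3A, SNORA53 and SNORA14B had -2.23, -2.07 and -1.74 in the authors' deposited table. That list was not called without RIP replicate 2 (adjusted p = 0.077) or with an estimated correlation (adjusted p = 0.723). Among 24 snoRNA host genes 13 fell and 1 rose in the authors' deposited table (the same counts adjusted over the list alone), with a median of -0.81, or -0.50 without RIP replicate 2 (limma camera, adjusted p = 0.0073, and adjusted p = 0.077 with an estimated correlation). SNHG6, SNHG29 and SNHG8 had -2.21, -1.57 and -1.22 in the authors' deposited table. With all 6 inputs the median was -1.79 and SNHG8 had -2.26, and at a mean count of at least 1000 the list was not called (adjusted p = 0.090).

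Metabolic and chaperone lists fell as lists but held members that rose. Of 33 glycolysis and hypoxia genes 20 fell and 9 rose in the authors' deposited table (20 and 10 adjusted over the list alone, median -0.76, limma camera adjusted p = 1.5e-05). The glycolytic enzymes GAPDH, TPI1 and GPI had -2.26, -1.77 and -1.58 in the authors' deposited table, whereas the secreted factors VEGFA (1.17 with all 6 inputs) and ADM had 2.09 and 2.45. Of 28 endoplasmic reticulum chaperone and unfolded protein response genes 17 fell and 6 rose in the authors' deposited table (17 and 7 adjusted over the list alone, median -0.64, limma camera adjusted p = 0.00029, and 0.094 under total-count scaling). The folding factors PDIA6, HYOU1 and CALR had -1.56, -1.45 and -1.44 in the authors' deposited table, while DNAJB9 had 1.91. Of 32 cholesterol and fatty acid synthesis genes 19 fell and 6 rose in the authors' deposited table (the same counts adjusted over the list alone, median -0.69, limma camera adjusted p = 0.0027). The enzymes ACLY and SCD had -1.29 and -1.13 in the authors' deposited table. That call did not hold with an estimated correlation (adjusted p = 0.274), under total-count scaling (adjusted p = 0.300), with all 6 inputs (adjusted p = 0.190) or at a mean count of at least 1000 (adjusted p = 0.139). Of 22 heat-shock genes 12 fell and 4 rose in the authors' deposited table (the same counts adjusted over the list alone, limma camera adjusted p = 0.014), with a median of -0.47 that became 0.021 under total-count scaling. HSP90AA1 and HSPD1 had -1.22 and -1.09 in the authors' deposited table, against 1.52 for DNAJB4 and 0.97 for DNAJB1. The heat-shock call was lost under total-count scaling (adjusted p = 0.300), with all 6 inputs (adjusted p = 0.985), at a mean count of at least 1000 (adjusted p = 0.132) and with shrunken folds (adjusted p = 0.217).

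Genes for protein turnover, replication and matrix followed the same direction. Of 43 proteasome genes 36 fell and 1 rose in the authors' deposited table (36 and 2 adjusted over the list alone), with a median of -0.93 (limma camera, adjusted p = 5.9e-12, and adjusted p = 0.099 with an estimated correlation). PSMB2 and PSMA7 had -1.55 and -1.53 in the authors' deposited table. Of 43 DNA replication genes 26 fell and 12 rose in the authors' deposited table (the same counts adjusted over the list alone, limma camera adjusted p = 0.011), with a median of -0.45 that became 0.050 under total-count scaling. POLD2 and TYMS, which act in DNA copying and nucleotide synthesis, had -1.29 and -1.25 in the authors' deposited table, and the cyclin CCNE1 had 1.19. The replication call was lost with an estimated correlation (adjusted p = 0.498), under total-count scaling (adjusted p = 0.932), at a mean count of at least 1000 (adjusted p = 0.161) and with shrunken folds (adjusted p = 0.156). Of 14 matrix and fibroblast marker genes 8 fell and 0 rose in the authors' deposited table (the same counts adjusted over the list alone, median -1.29, limma camera adjusted p = 0.00018). FN1, COL6A1 and VIM had -2.28, -1.49 and -1.47 in the authors' deposited table.

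A further 6 lists were not called. Decapping and P-body factors divided evenly, with 8 rising and 8 falling of 24 in the authors' deposited table (the same counts adjusted over the list alone, median -0.036, limma camera adjusted p = 0.884). In the authors' deposited table the decapping coactivators PNRC1 and PNRC2 rose by 2.14 and 1.48, whereas the poly(A)-binding protein PABPC1 and the Sm-like protein LSM4 had -1.34 and -1.77. Among 36 ATF4 and integrated stress response targets 10 rose and 18 fell in the authors' deposited table (11 and 19 adjusted over the list alone, adjusted p = 0.409 in limma's camera test). DDIT4 and the phosphatase subunit PPP1R15A rose by 1.91 and 1.82 and the serine synthesis enzyme PHGDH had -1.46 in the authors' deposited table. With all 6 inputs as 1 group and the authors' SE kept, that list was called below other genes (median -0.80, limma camera, adjusted p = 1.3e-07). PPP1R15A then had 0.78. The remaining inputs held the list's genes higher (median log2 ratio of compared to remaining inputs -0.86). Of 16 long non-coding RNAs, listed as nuclear-retained although NORAD, OIP5-AS1 and GAS5 are known as largely cytoplasmic, 4 rose and 6 fell in the authors' deposited table (the same counts adjusted over the list alone, limma camera adjusted p = 0.893), with NORAD at 1.57, OIP5-AS1 at 0.69 and GAS5 at -1.77 (-2.67 with all 6 inputs). The mitotic list had 4 rising and 9 falling of 34 in the authors' deposited table (the same counts adjusted over the list alone, limma camera adjusted p = 0.363), with BIRC5 at -1.08, CDC20 at -0.85 and AURKB at -0.75, which was not called under total-count scaling (-0.26). Interferon-stimulated genes had 3 rising and 4 falling of 37 in the authors' deposited table (the same counts adjusted over the list alone, limma camera adjusted p = 0.816), with IFIT5 at 1.35 and IRF1 at 1.38. Epithelial markers had 2 falling of 9 in the authors' deposited table (the same count adjusted over the list alone, limma camera adjusted p = 0.437), with KRT18 at -0.78 and ITGB4 at -1.12, and KRT8, at -0.70, did not pass. Under total-count scaling KRT18 (-0.28) and ITGB4 (-0.62) were not called, and KRT8 was called at a CPM of at least 1 and without RIP replicate 1 (-0.87) or 3 (-0.75). Blood cell markers had 4 tested members, too few for the list test, and 0 of them passed in the authors' deposited table.

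By class, 3793 of 14382 protein-coding genes were enriched and 3752 depleted in the authors' deposited table. Of 4438 long non-coding RNAs, 399 were enriched and 127 depleted in the authors' deposited table. Of 972 processed pseudogenes 133 fell and 15 rose in the authors' deposited table. Small nuclear RNAs had 21 depleted and 0 enriched of 49, and mitochondrial transfer RNAs 13 depleted and 0 enriched of 15, in the authors' deposited table.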

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

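Counts, lists and named genes were set against the alternatives that could be computed, of which shrunken folds, the adjusted p under 0.01, the mean normalized count of at least 1000, protein-coding genes alone, ranks and shrunken folds in the list test were chosen after seeing the data. No paired analysis was possible because the input columns could not be assigned to samples. For the same reason the planned quasi-likelihood and other count refits, the relative log expression scaling, the fit of 9 libraries, the replicate block, fry, the comparison with each kind of input, omission of input libraries, splits of the samples by chance and every planned doxycycline comparison were not run. Under total-count scaling the counts became 6994 enriched and 2055 depleted, and 4392 and 817 at least 2-fold, because the scaling adds the same shift to every fold. With a mean normalized count of at least 1000, 2508 genes were enriched, and 860 enriched and 1077 depleted at least 2-fold, with fewer genes tested (7254). The other counts stayed within 1.5 times the main ones, and without each RIP library, with the authors' SE kept, 4172 to 4365 genes were enriched and 4026 to 4427 depleted. Without RIP replicate 2, 3897 of the enriched and 3756 of the depleted genes were shared with the main calls. CNOT7 kept its direction and call in every setting run. The setting with all 6 inputs pools cells with and without doxycycline, so it changes the reference and not only the processing. Reversed values were CNOT3 (0.47), CNOT10 (0.092) and CNOT11 (0.13) under total-count scaling, which follows from the added shift, and the p53 list with all 6 inputs (adjusted p = 0.185), where the remaining inputs held its genes higher (median log2 ratio -1.28). For named genes 1257 of the values kept direction and call, 11 lost the call and 12 gained it. For lists 357 values did, 19 lost the call and 1 gained it. An estimated correlation alone removed the call of 6 lists. Others kept it with a larger adjusted p (limma camera), such as 1.1e-06 for AU-rich and immediate-early mRNAs. Zinc finger genes had 1.9e-09 and HOX genes 0.00025 in that test. Genes under about 1000 reads were measured unevenly in RIP replicate 2, although it is the deepest RIP library, and the depth of the input libraries was not analysed here.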

Other observations

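Here the families below, the comparison of input sets, the tests on RIP replicate 2 and the test on CNOT6 and CNOT6L were chosen only after the result was seen. Regulatory gene families outside the fixed lists were enriched as well, by the counts in the authors' deposited table and limma's camera test adjusted over 20 families. Of 40 ZBTB zinc finger genes 38 rose and 0 fell (adjusted p = 5.3e-19), with ZBTB7A at a log2 fold of 1.60 in the authors' deposited table. Of 36 forkhead genes 26 rose and 0 fell (median 1.20, adjusted p = 6.5e-13), with FOXB1 at 2.23 and FOXC1 at 1.73 in the authors' deposited table. Of 13 SOX genes 11 rose (median 1.20, adjusted p = 6.5e-06) and of 10 Frizzled receptors 9 rose (median 1.06, adjusted p = 7.2e-05). KLHL (18 rose and 1 fell of 31), F-box (14 and 4 of 32) and RING finger (33 and 12 of 71) genes were also called above other genes.

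Several housekeeping families went below other genes in limma's camera test. Of 17 cytosolic tRNA synthetase genes 15 fell and 0 rose in the authors' deposited table (median -0.74, adjusted p = 4.4e-10, and adjusted p = 0.031 with an estimated correlation), with QARS1 at -1.71. Of 8 coatomer genes 7 fell in the authors' deposited table (median -0.85, adjusted p = 4.0e-05). The CCT chaperonin (8 of 9), Sm and snRNP protein (11 of 16) and V-ATPase (9 of 18) genes that fell formed calls that did not hold with an estimated correlation (adjusted p = 0.085, 0.085 and 0.130). WNT ligands, protocadherins, kinesins, RAB GTPases, solute carriers, RNA polymerase subunits, mitochondrial tRNA synthetases and replication-independent histones were not called.

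The 3 compared inputs and the remaining 3 inputs could be set apart as derived means without SDs over 14552 genes, and the sources used here do not say which set had doxycycline. CNOT7 stood at 24800 normalized counts in the compared set and 4240 in the remaining one, a ratio of 5.85. If doxycycline induces tagged CNOT7, the compared set would be the treated one. The differences below would then be those of treated against untreated cells, which was not tested. HSPA1B stood at 7172 and 809, SNHG1 at 2361 and 22623, ATF3 at 1424 and 7871, and CDKN1A at 914 and 4446. Median log2 ratios of the compared to the remaining set were -1.28 for p53 targets, -1.06 for replication-dependent histones, -1.02 for snoRNA host genes, -0.86 for ATF4 targets, -0.55 for HOX genes, -0.32 for ribosomal proteins, -0.24 for zinc finger genes, 0.38 for mitochondrially encoded genes and 0.74 for heat-shock genes. The negative ones lay below and the positive ones above all of 10000 random lists matched on input level, which describes these libraries and is no test.

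RIP replicate 2 had no reads for many genes that the other RIP libraries detected. Lower depth is argued against, since its total was 1.08 times the mean of the others. Over 1313 genes with reads in all 3 and 30 to 100 on average in the others, the SD of its log2 ratios to them was 3.16 times that between them. Genes dropped whole in counting would not widen this spread but genes counted in part would, so different counting stays open. A small number of distinct RNA molecules behind this library may account for it: among genes at 1 to 10 reads elsewhere with a read in replicate 2, 27.4% had 20 or more, against 2.73% for replicate 3 set against replicate 1. That share lies between the bounds set for this explanation (over 50% or under 5%), so it stays open, and no biological explanation was tested.

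The place of AU-rich, zinc finger and ribosomal protein mRNAs could reflect how abundant they were in input. The medians of the first 2 of these lists lay at percentile 100 of 10000 random lists matched on derived input level, and that of ribosomal proteins at percentile 0, which argues against abundance alone. Random lists matched to ribosomal proteins had a median of -0.73. They were drawn from all tested genes, the ribosomal protein genes included. How much of that list's -1.94 goes with input level is therefore not shown. Among lists called below other genes, heat-shock, DNA replication and endoplasmic reticulum chaperone genes lay at percentiles 20.9, 7.39 and 2.78. For these lists abundance alone stays open. Short transcripts could be lost in RIP, so genes spanning at most 3000 bp were compared. Among them 12 AU-rich and immediate-early genes had a median of 2.25 and 16 ribosomal protein genes -2.01. The difference was 4.26 (2-sided permutation test, p = 0.0001). That p-value treats genes as independent, although ribosomal protein genes vary together (estimated correlation 0.54). The whole lists also lay apart, so the p-value does not speak for transcript length. The span only caps transcript length, and lengths below that cap were not examined here. A loss of short transcripts therefore stays open. Nonspecific recovery stays open, as no immunoprecipitate from untagged cells was analysed here.

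CNOT1 and CNOT7 mRNAs were the most abundant RNAs in the RIP mean and ranked 61 and 119 in the derived input. Input level alone is argued against, since CNOT1 lay at percentile 100 of the 200 genes nearest in input level, with 2.03 in the authors' deposited table against their median of -1.17. Its first rank in RIP does not fix this, as 164 of them had a lower input and so room for a larger fold. A candidate explanation is that tagged CNOT7 bound subunits still being made on their own mRNAs. CNOT6 and CNOT6L, whose proteins sit beside CNOT7, had a mean log2 fold of 0.27, against a median of 0.30 and a highest value of 0.95 for 7 other subunits, and neither passed the test in the authors' deposited table, though both did in 4 alternatives (0.76 and 0.77 under total-count scaling). CNOT6 and CNOT6L thus did not lie above the other subunits, as this explanation was taken to predict. Neither was called below 0, the bound set against it. The explanation stays open for CNOT1 and CNOT7, also because no immunoprecipitate from untagged cells was analysed here. For CNOT7, reads from the tagged transgene stay open too, as gene counts do not separate them. CNOT7 stood at 24800 normalized counts in the compared inputs and 4240 in the remaining ones. That would place doxycycline with the compared inputs if it induces tagged CNOT7, but which set had doxycycline is not given.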
